A study of Homo sapiens with 10 samples.

How the data were processed

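RNA was sequenced as paired-end libraries from CD4 T cells sorted from human tonsil. The sort used antibodies against CD4, CD45RA, the T cell receptor beta chain, PD-1 (encoded by PDCD1), CXCR5 and PSGL-1 (encoded by SELPLG), per the labels' protocols. The NAIVE gate took CD45RA-positive cells high in PSGL-1 (4 libraries). The TFH gate took CD45RA-negative cells high in PD-1 and CXCR5 and low in PSGL-1 (3 libraries). The TEFF gate took CD45RA-negative cells low in PD-1 and CXCR5 and high in PSGL-1 (3 libraries). Groups and replicate numbers came from the sample titles. The labels do not say which libraries came from the same tonsil, so p-values measure only the spread between these libraries, which may be partly technical.

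A pair of deposited tables was used. The first holds the count of reads per gene made by the authors, as whole numbers for 23345 gene symbols, with 5 further rows for reads assigned to no gene. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.4, HTSeq, edgeR and the hg19 genome build, with no role or order for each, and strandedness is not given in the sources used here. Reads from overlapping or antisense genes, and from near-identical copies such as CD8B and its paralog, therefore cannot be told apart with certainty. The second table holds log2 RPKM values deposited by the authors. These values were found to be scaled to all counted reads, with the no-gene rows included and a small count added before the logarithm. The scaling of each library, averaged over 1697 genes, differed from that of all counted reads by at most 8.8e-06 on the log2 scale. This check covers the scaling of libraries only, not gene length or the added count. The alternatives on RPKM therefore used 2 to the power of the deposited value, plus a pseudocount of 1 or 0.1, because the deposited unit was log2 and not linear RPKM as first assumed. No coordinates are given, since the annotation at hand is of another build than hg19.

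The rows that name no gene were kept out of library sizes and tests. They took between 22.3% and 38.3% of all counts in a library. Gene counts ranged from 20424112 to 41987860 per library. A count of 0 allows an expression of up to 0.0714 CPM in the deepest library and 0.147 CPM in the shallowest, taking 3 counts as the limit. This limit covers counting error only. The summed gene counts fall into a deeper and a shallower set of 5 libraries each, and every group has libraries in both sets.

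Differential expression was tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood F test on counts, TMM normalisation and the default expression filter (a minimum count of 10), which kept 14960 genes. All 10 libraries entered 1 fit with the group as the only term, and each pair of groups was a contrast in it. P-values were adjusted by the Benjamini-Hochberg method over all genes tested and called below 0.05. Standard errors were taken as the size of the log2 fold change divided by the square root of the F statistic. CPM values use TMM-normalised library sizes and are given as mean ± SD over the libraries of a group. Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over 27 lists, and again with an estimated correlation. The lists hold 461 members, 460 of them in the table and 3 under another symbol. List members were also counted with p-values adjusted over the list alone.

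Groups, lists, tests, alternative settings and the rule for named genes were fixed before the data were examined. The rule names the sorting markers CXCR5, PDCD1, SELPLG and CD4, and BCL6, PRDM1, MAF, IL21, CXCL13, TBX21, GATA3, FOXP3, TCF7, LEF1 and KLF2 whatever their values. For each comparison it adds the 10 largest positive and 10 largest negative log2 fold changes among called genes with at least 20 CPM in the higher group and no overlap between the libraries of both groups. For each list it adds up to 3 called members with the largest change in the majority direction and up to 2 in the other direction, or the member with the highest mean CPM where none was called. HLA genes, antigen receptor segments and sex-linked genes that differ between donors were left out of the second part. The text prints a selection of these genes, and some that the rule names are not reported here.

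The alternatives chosen then were RLE size factors, DESeq2 1.42.0, limma voom, no expression filter, a filter of 10 CPM in 3 libraries, fits with only the compared groups, the replicate number as a block, the RPKM values, each library left out in turn, camera with an estimated correlation, and fry. Alternatives chosen after seeing the data were the library set as a covariate, each library set alone, that covariate with TEFF replicate 2 left out, and NAIVE replicates 1, 3 and 4 left out. Library pairs within a group differed by more than counting noise, with a chi-square per degree of freedom of at least 59.5, so none was taken as a duplicate.

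The gene and list tests were first tested on simulated data, with 200 genes changed in counts drawn from the real means, library sizes and dispersions. For TFH against TEFF, on 14753 simulated genes, 1.49% of the genes changed 2-fold, 56.7% of those changed 4-fold and 75.8% of those changed 8-fold were recovered. For TFH against NAIVE, on 14745 genes, the shares were 5.97%, 56.7% and 84.8%. For TEFF against NAIVE, on 14735 genes, they were 7.46%, 53.7% and 80.3%. False calls numbered 3, 5 and 3 in the same order. In each comparison the simulated list of shifted genes was recovered in its direction. The counts were drawn independently for each gene, so this does not test the preset correlation on lists whose members vary together.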

Results

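The transcriptomes of 3 CD4 T cell populations of human tonsil were measured by RNA sequencing. They were follicular helper cells (TFH, n = 3), which help B cells in germinal centres, non-follicular effector cells (TEFF, n = 3) and naive cells (NAIVE, n = 4). Gene counts per library were 20424112 to 41987860 in NAIVE, 22240070 to 34510430 in TEFF and 26904731 to 41217246 in TFH. The first principal component held 41.0% of the variance and ordered the groups, with NAIVE between -71.6 and -61.1, TEFF between 2.54 and 33.3, and TFH between 75.2 and 76.6. TEFF replicate 2 took the value 33.3 and lay nearer to TFH than TEFF replicates 1 (3.22) and 3 (2.54). The second component held 23.3% and followed library depth, at 12.5 to 82.5 in the 5 deeper libraries and -60.3 to -6.28 in the 5 shallower ones. Reads outside genes made up 15.9% to 22.6% of counts in the deeper libraries and 26.2% to 29.2% in the shallower ones.

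**Figure D1:**
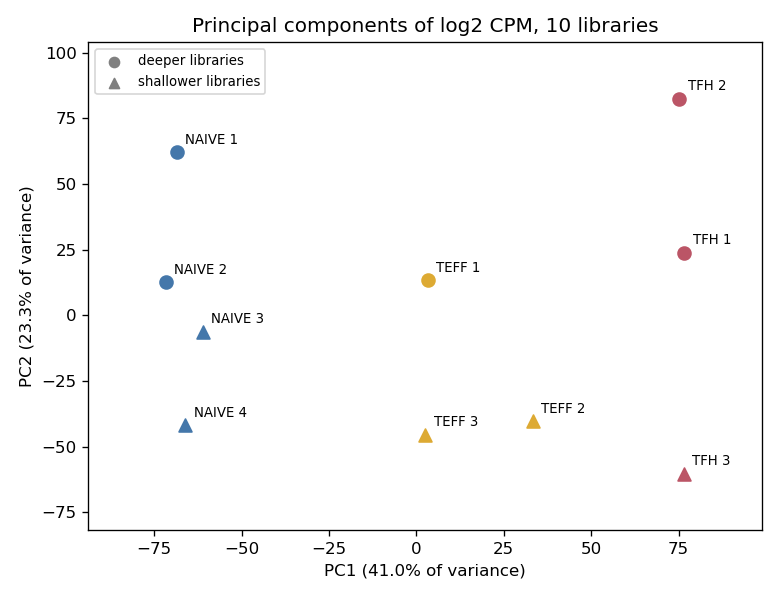
Principal components of log2 CPM, with the first on the x axis, the second on the y axis, colour for the group and marker shape for the library set. NAIVE, TEFF and TFH libraries follow one another along the first component, which holds 41.0% of the variance, and the deeper and shallower libraries part along the second, which holds 23.3%.

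The comparison of TFH with TEFF asks what sets follicular helper cells apart from other antigen-experienced cells of the same tissue. The TFH libraries held less mRNA for the regulators FOXP3 and PRDM1, whereas TBX21 and GATA3, the lineage factors of Th1 and Th2 cells, were not called. FOXP3, the lineage factor of regulatory T cells, fell by 4.10 on the log2 scale (SE 0.55), from 106 ± 33.1 CPM in TEFF to 6.17 ± 5.20 CPM in TFH (SD, n = 3 each, adjusted p = 0.0183 by edgeR). PRDM1, which encodes the BCL6 antagonist Blimp-1, fell by 2.85 (SE 0.44), from 91.7 ± 31.6 to 12.7 ± 3.98 CPM (adjusted p = 0.0183). In the opposite direction KCNK5, a potassium channel, rose by 2.12 (SE 0.38), from 112 ± 59.98 to 487 ± 19.8 CPM (adjusted p = 0.0355). CAV1 (log2 fold change 3.63, adjusted p = 0.0486), the Wnt ligand gene WNT10A (2.12, adjusted p = 0.036) and the histone variant gene H2AFZ (1.41, adjusted p = 0.0313) also rose. Of 14960 genes, 18 were higher and 124 lower in TFH. All 142 had no overlap between the libraries of both groups, as did 18.9% of all genes tested, where chance gives 10%.

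The sorting markers and the follicular regulators did not pass the threshold over all genes. With TEFF replicate 2 left out, 6 genes named by the rule gained a call in this comparison and 3 lost it. A missing call here therefore does not show equal levels. CXCR5 stood at 2116 ± 429 CPM in TFH and 676 ± 377 in TEFF (log2 fold change 1.65, SE 0.46, adjusted p = 0.139), and PDCD1 at 2398 ± 279 and 533 ± 480 (2.17, SE 0.57, adjusted p = 0.117). These genes check the labels, since the cells were chosen by their proteins. SELPLG (-1.45, adjusted p = 0.143) was not called, nor was CD4 (0.34, adjusted p = 0.578), on which both groups were gated alike. BCL6, the lineage factor of TFH cells, was at 596 ± 119 CPM in TFH and 211 ± 131 in TEFF (2.82-fold, adjusted p = 0.153). CXCL13, a chemokine that draws B cells, was at 246 ± 133 and 63.9 ± 78.8 (1.95, adjusted p = 0.326), and IL21 at 41.1 ± 23.7 and 19.4 ± 12.5 (1.08, adjusted p = 0.475). The libraries of TEFF differed for these genes: TEFF replicate 2 had 1107 CPM of CXCR5, against 510 and 410 in TEFF replicates 1 and 3, 1087 CPM of PDCD1 against 261 and 249, and 155 CPM of CXCL13 against 18.3 and 18.5.

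**Figure D2:**
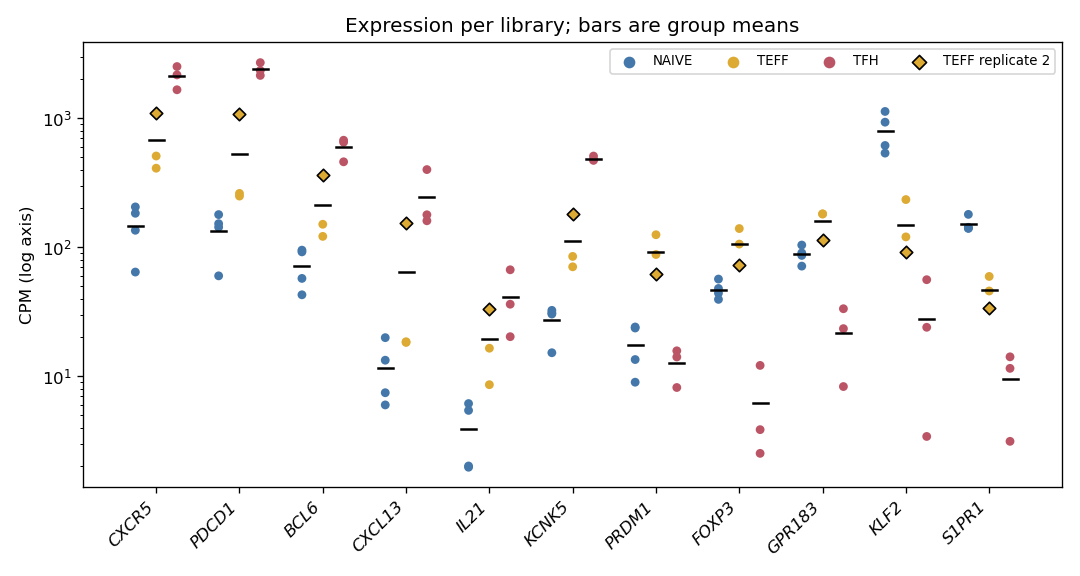
CPM on a log axis for 11 genes, with a point for each library, colour for the group, bars for group means and a diamond for TEFF replicate 2. For CXCR5 the diamond, at 1107 CPM, lies between the other TEFF libraries (410 and 510 CPM) and the TFH libraries (1663 to 2517 CPM).

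Among the fixed lists, 16 were called in TFH against TEFF with the preset correlation, and 6 held with an estimated correlation, each at adjusted p = 0.0442. Those 6 were all lower in TFH. They are not independent, since some share members. CXCR6 is in the trafficking and Th1 lists, S1PR1 in the trafficking and naive lists, and IL1R1 in the Th17 and cytokine receptor lists. In the Th17 list (median log2 fold change -3.49), 4 of 12 members fell, 0 rose and 8 were not called, and 10 were lower when adjusted over the list alone. IL17A fell by 5.35 (adjusted p = 0.0355), IL26 by 4.53 (adjusted p = 0.0383) and CCL20 by 3.85 (adjusted p = 0.0293). Their means were 6.02, 1.45 and 4.57 CPM in TEFF, and 0.142, 0.0596 and 0.31 CPM in TFH. For IL17A and IL26 the TFH means lie near the limit for a count of 0, so the size of these falls is uncertain. In the trafficking receptors 4 of 24 fell and 20 were not called (16 lower and 1 higher adjusted over the list alone), with CXCR6 falling by 3.99 and GPR183, an oxysterol receptor that positions cells outside follicles, by 2.87, from 159 ± 39.4 to 21.7 ± 12.6 CPM. In the naive and quiescence list 3 of 20 fell and 17 were not called (13 lower and 2 higher adjusted over the list alone), with S1PR1, an egress receptor, falling by 2.27. In the Th1 list 3 of 15 fell, among them IL18RAP (by 3.45) and IL18R1 (by 2.51), and 12 were not called (5 lower and 1 higher adjusted over the list alone). In the cytokine receptors 5 of 25 fell, with IL1R2 falling by 4.91 and IL1R1 by 3.50, and 20 were not called (10 lower adjusted over the list alone). In the factors opposing TFH differentiation PRDM1 and IL2RA fell, 12 of 14 were not called, and 7 were lower adjusted over the list alone. TBX21 (-0.24, adjusted p = 0.798) and GATA3 (-0.20, adjusted p = 0.78), the lineage factors of Th1 and Th2 cells, were not called.

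The other 10 lists lost the call with an estimated correlation. The Tfh programme list had a median of 0.88, with 0 of 24 members called over all genes by edgeR and 6 higher adjusted over the list alone (adjusted p = 3.39e-08, and adjusted p = 0.114 with an estimated correlation). In the Treg list 5 of 14 members fell and 9 were not called (7 lower adjusted over the list alone), with LRRC32 falling by 4.90 (adjusted p = 0.0957 with an estimated correlation). B cell markers had a median of 2.31 with 0 of 15 called, also over the list alone (adjusted p = 0.306 with an estimated correlation). CD79A, a B cell receptor subunit gene, was at 187 ± 12.7 CPM in TFH and 31.5 ± 35.2 in TEFF (adjusted p = 0.231). Cell cycle (median 0.64, 0 of 34 called, adjusted p = 0.313 with an estimated correlation), germinal centre B cell markers (1.35, 0 of 11, adjusted p = 0.323 with an estimated correlation), and CD8 and NK cell markers (1.18, 0 of 5, 1 higher over the list alone, adjusted p = 0.306 with an estimated correlation) had positive medians. CD8B stood at 49.9 ± 7.13 CPM in TFH and 7.96 ± 10.5 in TEFF (adjusted p = 0.168), and its reads may be shared with a near-identical copy. Glycolysis (0.49, 0 of 22 called, 6 higher and 1 lower over the list alone, adjusted p = 0.465 with an estimated correlation) and cholesterol biosynthesis (0.32, 0 of 21, 2 higher over the list alone, adjusted p = 0.306 with an estimated correlation) were positive. In the shallower libraries alone the cell cycle median turned to -0.30 and that of glycolysis to -0.049. Interferon stimulated genes (-0.54, 0 of 20 called, 1 lower over the list alone, adjusted p = 0.465 with an estimated correlation) and cytotoxic granule and chemokine genes (-0.79, 0 of 14, 1 higher and 3 lower over the list alone, adjusted p = 0.465 with an estimated correlation) were negative. Lists without a call were the sorting markers (adjusted p = 0.0721), Th2 (0.0926), plasma cell markers (0.0926), TCR signalling core (0.111), stromal and endothelial markers (0.111, with CAV1 higher), myeloid and dendritic cell markers (0.253), immediate early (0.305), heat shock (0.472), costimulatory and inhibitory receptors (0.627), red cell markers (0.856) and epithelial markers (0.918). Adjusted over the list alone, 2 sorting markers, 1 TCR signalling gene, 2 stromal, 1 immediate early and 2 costimulatory genes were higher. For the epithelial markers the median and mean were positive and the camera direction negative. Over the list alone 1 sorting marker, 1 Th2 gene, 1 plasma cell marker, 2 immediate early and 2 costimulatory genes were lower.

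The counts for TFH against TEFF rested on single libraries and on the fit. With only both groups in the fit, edgeR called 0 genes (1665 at an unadjusted p under 0.05, against 1985 in the fit of 10 libraries, and 255 higher and 434 lower with DESeq2). Without TEFF replicate 1 or TEFF replicate 3 it also called 0 (1389 and 1187 at an unadjusted p under 0.05). Without TEFF replicate 2 it called 162 higher and 194 lower, of which 11 and 121 were among those called with it. The library set as a covariate gave 90 and 282. Leaving out TFH replicates 1, 2 or 3 gave 3 and 19, 6 and 79, or 7 and 51, and leaving out NAIVE replicates 2, 3 or 4 gave 13 and 66, 6 and 66, or 5 and 62. Within the deeper or the shallower set alone 0 genes were called (1055 and 1571 at an unadjusted p under 0.05). These sets hold 1 TEFF and 1 TFH library, respectively, and the lone library was assumed to vary like the other groups.

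The comparison of TFH with NAIVE gives the full distance between the follicular and the unstimulated state. In the Tfh programme list 20 of 24 members were higher, 0 lower and 4 not called (22 higher adjusted over the list alone), with a median log2 fold change of 2.64. Its camera test gave adjusted p = 2.94e-19, and the call was lost at adjusted p = 0.0607 with an estimated correlation. BCL6 rose by 3.05 (SE 0.41), from 71.8 ± 25.8 CPM in NAIVE (n = 4) to 596 ± 119 in TFH (n = 3, adjusted p = 7.40e-04 by edgeR). CXCL13 rose by 4.40 (SE 0.79), from 11.7 ± 6.34 to 246 ± 133 CPM (adjusted p = 0.00351), and MAF, a transcription factor of IL21-producing cells, by 3.16 (SE 0.38), from 169 ± 91.5 to 1508 ± 146 (adjusted p = 4.73e-04). The largest positive changes included GNG4 (4.88), HAL (4.84), PVALB (4.54), MYO7A (4.41) and the neurotrophin receptor gene NTRK3 (4.34). Among the sorting markers PDCD1 rose by 4.17 and CXCR5 by 3.85, and SELPLG fell by 1.72, in the direction of the gates. CD4, on which all groups were gated alike, rose by 1.02 (3 higher and 1 lower adjusted over the list alone, adjusted p = 0.258 for the list with an estimated correlation). Of 14960 genes, 1375 were higher and 1248 lower.

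Genes of naive and resting T cells fell in TFH. In the naive and quiescence list 16 of 20 were lower, 1 higher and 3 not called, which are the counts adjusted over the list alone as well (adjusted p = 1.61e-16, and 0.0146 with an estimated correlation). Of the 15 lists called with the preset correlation, only this 1 held with an estimated correlation. KLF2, which restrains TFH differentiation and drives S1PR1, fell by 4.85 (SE 0.83), from 803 ± 277 to 27.8 ± 26.5 CPM. NELL2 fell by 6.23, CCR7, a lymph node homing receptor, by 3.27 and LEF1 by 2.53, whereas ID3 rose 2.83-fold and TCF7 was not called (0.06, adjusted p = 0.901). The trafficking receptors had 7 of 24 lower, 3 higher and 14 not called (12 and 4 adjusted over the list alone, adjusted p = 0.532 with an estimated correlation), with S1PR1 falling by 3.97 and ITGAL rising by 1.45. The factors opposing TFH differentiation had 6 of 14 lower and 1, IL2RB, higher (6 and 2 adjusted over the list alone, adjusted p = 0.328 with an estimated correlation), with RUNX3 falling by 2.78 and BACH2 by 2.43, while PRDM1 was not called (-0.47, adjusted p = 0.458).

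Surface receptors and metabolic genes moved in part. Of the costimulatory and inhibitory receptors 7 of 23 rose and 3 fell (11 and 3 adjusted over the list alone, adjusted p = 0.077 with an estimated correlation), with TIGIT rising by 3.44, TNFRSF18 by 3.37 and CD200 by 2.78, and CD244 falling by 3.05. In glycolysis 6 of 22 rose and 2 fell (9 and 2 adjusted over the list alone, adjusted p = 0.61 with an estimated correlation), with PFKFB3 rising by 2.27 and HK2 falling by 1.75. In cholesterol biosynthesis 4 of 21 rose, also adjusted over the list alone (adjusted p = 0.525 with an estimated correlation), among them SREBF2, the regulator of sterol synthesis, by 1.72. In the cell cycle list 3 of 34 rose (2 adjusted over the list alone, adjusted p = 0.61 with an estimated correlation), with PLK1 rising by 1.69, and its median turned from 0.66 to -0.28 in the shallower libraries alone. The cytotoxic granule and chemokine list had 5 of 14 lower and PRF1 higher (9 and 1 adjusted over the list alone, adjusted p = 0.571 with an estimated correlation). Lists without a call were TCR signalling core (6 of 23 higher and 1 lower, adjusted p = 0.0613), interferon stimulated (1 higher and 3 lower of 20, 0.0756), Th17 (1 and 1 of 12, 0.12), and heat shock (0 and 1 of 13, 0.216). Others were stromal and endothelial markers (2 and 3 of 6, 0.27), cytokine receptors (5 and 6 of 25, 0.30), immediate early (1 and 2 of 21, 0.392), Treg (4 and 5 of 14, 0.658), Th2 (1 and 1 of 7, 0.928), Th1 (5 and 3 of 15, 0.987), epithelial markers (0 and 1 of 7, 0.987) and red cell markers (0 and 0 of 2, 0.987). In the Treg, Th2 and red cell lists the median and mean were negative and the camera direction positive. Adjusted over the list alone, the counts that differed from these were 7 higher and 2 lower in TCR signalling, 0 and 0 in heat shock, 2 and 4 in stromal markers, 5 and 9 in cytokine receptors, 5 and 5 in Treg, and 6 and 6 in Th1. Immediate early genes, which respond within minutes to stimulation or handling, had a mean of 8.06 log2 CPM in the 5 deeper libraries and 6.74 in the 5 shallower ones (difference 1.32, exact two-sided permutation p = 0.0159 over 252 splits, chosen after seeing the data).

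B cell transcripts differed among the NAIVE libraries. CD22, a B cell surface lectin, was at 209, 140.3 and 96.3 CPM in NAIVE replicates 1, 3 and 4 and at 10.9 CPM in NAIVE replicate 2. B cell markers had 2 of 15 lower in TFH over all genes (12 lower and 1 higher adjusted over the list alone), germinal centre B cell markers 3 of 11, plasma cell markers 6 of 10 with XBP1 higher, and myeloid and dendritic cell markers 3 of 14. None of these lists held with an estimated correlation (adjusted p = 0.61, 0.532, 0.537 and 0.532). Adjusted over the list alone, the last 3 lists had 5, 8 and 6 lower, and 2 plasma cell markers were higher. CD8 and NK cell markers had 3 of 5 higher, with CD8B rising by 2.85 and FCRL6 by 3.07 (3 also adjusted over the list alone, adjusted p = 0.484 with an estimated correlation). The counts with NAIVE replicates 1, 3 and 4 left out were 189 higher and 240 lower, and without NAIVE replicate 2 they were 915 and 1061. With NAIVE replicate 2 as the lone NAIVE library, assumed to vary like the other groups, the B cell markers turned to a median of 0.56 from -2.47, and the germinal centre B cell markers to 0.78 from -1.29. Without TFH replicate 3 the number of called lists was 7 instead of 15. Leaving out TFH replicate 1 gave 943 and 831, and the shallower set, with 1 TFH library assumed to vary like the other groups, and the deeper set gave 495 and 699, and 436 and 387.

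**Figure D3:**
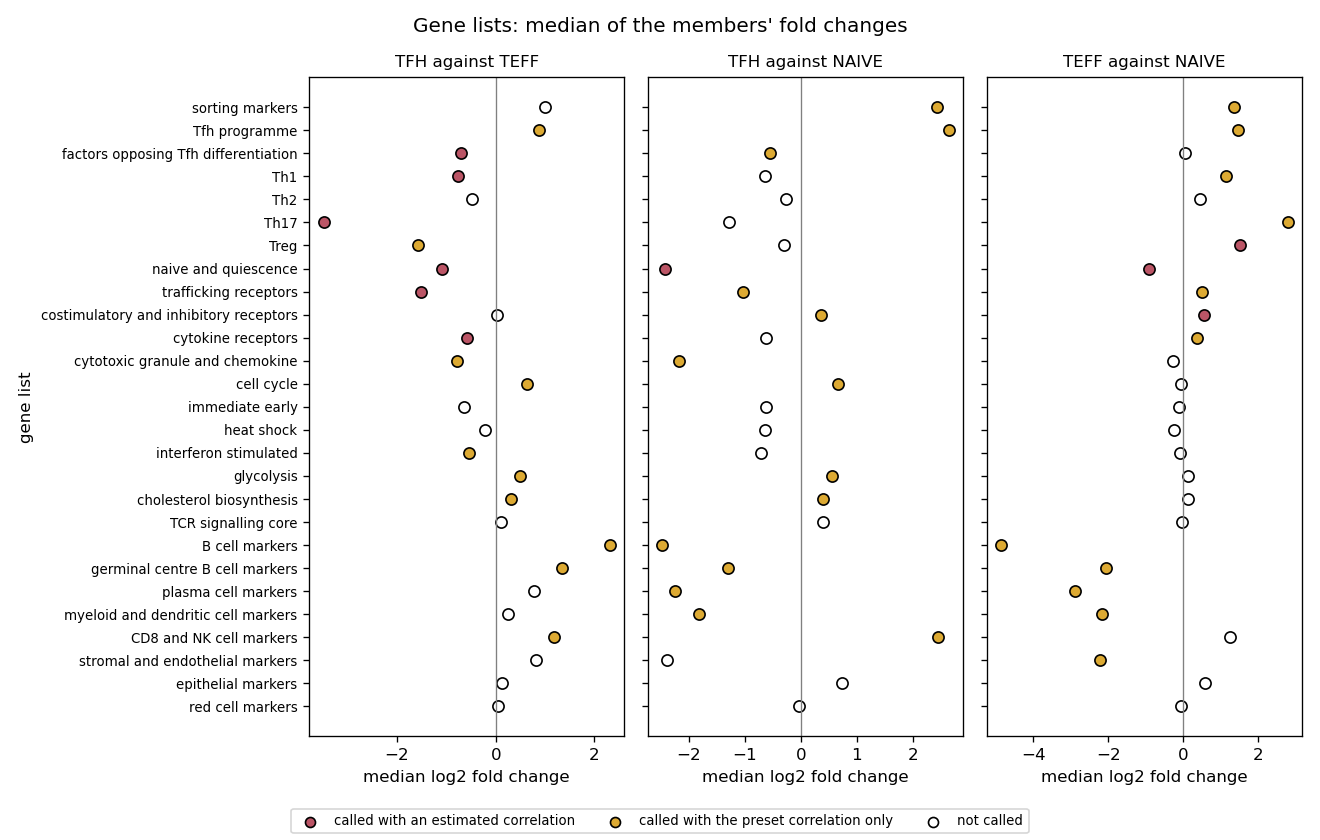
Median log2 fold change of each of 27 gene lists (y axis) in the 3 comparisons, with colour for the camera call at adjusted p below 0.05. Th17 and 5 other lists are called in TFH against TEFF with an estimated correlation, and B cell markers have a median of -4.85 in TEFF against NAIVE.

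The comparison of TEFF with NAIVE shows which changes the effector gate shared with the follicular one and which it did not. KLRB1, a lectin receptor found on Th17 cells, rose by 3.32 (SE 0.44), from 13.7 ± 6.02 CPM in NAIVE (n = 4) to 137 ± 30.1 in TEFF (n = 3, adjusted p = 0.00405 by edgeR), and PRDM1 by 2.39 (SE 0.39), from 17.6 ± 7.52 to 91.7 ± 31.6 CPM (adjusted p = 0.00785). TBX21 rose by 2.08 (adjusted p = 0.00809), while FOXP3 (1.18, adjusted p = 0.193) and GATA3 (0.68, adjusted p = 0.183) were not called. Among follicular genes MAF rose by 2.78, TIGIT by 2.13, CXCR5 by 2.20, BCL6 by 1.56 and IL21 by 2.32, while the Tfh programme list lost its call with an estimated correlation (adjusted p = 0.0529). Without TEFF replicate 2 the log2 fold changes of CXCR5, BCL6 and IL21 were 1.65, 0.93 and 1.70 and were not called (adjusted p = 0.0647, 0.242 and 0.198). CXCL13 did not pass (2.46, adjusted p = 0.0888), nor did KLF2 (-2.43, adjusted p = 0.0851). Of 14960 genes, 412 were higher and 421 lower.

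By list, the Tfh programme had 11 of 24 higher and 13 not called (17 higher adjusted over the list alone, adjusted p = 8.25e-16, and adjusted p = 0.0529 with an estimated correlation). Th17 had 6 of 12 higher and 1, ABCB1, lower (8 and 1 adjusted over the list alone, adjusted p = 0.068 with an estimated correlation), with IL1R1 rising by 3.82 and IL17A by 3.49. Th1 had 6 of 15 higher (7 higher and 3 lower adjusted over the list alone, adjusted p = 0.0529 with an estimated correlation), with CXCR6 rising by 3.10. Treg had 5 of 14 higher (9 adjusted over the list alone) and held with an estimated correlation (adjusted p = 0.0396), with LRRC32 rising by 2.55 and TNFRSF4 by 2.23. Naive and quiescence genes, with 7 of 20 lower (10 adjusted over the list alone), and costimulatory and inhibitory receptors, with 7 of 23 higher and 2 lower (10 and 2), also held (adjusted p = 0.0152 and 0.0192 with an estimated correlation). LRRN3 fell by 4.55, NOG by 4.41 and LEF1 by 1.61, and LAG3 rose by 2.34. Sorting markers had 2 of 4 higher (3 adjusted over the list alone, adjusted p = 0.113 with an estimated correlation), cytokine receptors 6 of 25 higher and 1 lower (7 and 2, adjusted p = 0.116), and trafficking receptors 4 of 24 higher and 2 lower (8 and 4, adjusted p = 0.381 with an estimated correlation). Lists without a call were Th2 (1 higher and 1 lower of 7, adjusted p = 0.0773), cytotoxic granule and chemokine (0 and 1 of 14, 0.122), cholesterol biosynthesis (0 of 21, 0.162), heat shock (0 of 13, 0.244), TCR signalling core (1 of 23 higher, 0.244), CD8 and NK cell markers (0 of 5, 0.381), glycolysis (2 and 1 of 22, 0.577), factors opposing TFH differentiation (4 and 2 of 14, 0.607), immediate early (0 of 21, 0.841), and cell cycle, interferon stimulated, epithelial and red cell lists (0 of 34, 20, 7 and 2, each 0.949). Adjusted over the list alone, the counts that differed from these were 2 higher and 1 lower in Th2, 0 and 3 in the cytotoxic list, 1 and 0 in the CD8 and NK list, and 4 and 3 in the factors opposing TFH differentiation. The cell cycle, interferon stimulated and TCR signalling lists had a negative median and a positive camera direction, and of these only TCR signalling had a positive mean.

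In the B cell marker list 12 of 15 fell in TEFF and 0 rose (13 lower adjusted over the list alone, adjusted p = 8.25e-16, and adjusted p = 0.108 with an estimated correlation), with CD22 falling by 5.31 (SE 1.07), from 114 ± 83.1 to 2.89 ± 1.37 CPM. Germinal centre B cell markers had 6 of 11 lower (adjusted p = 0.068 with an estimated correlation), plasma cell markers 5 of 10 (adjusted p = 0.121), myeloid and dendritic cell markers 4 of 14 (adjusted p = 0.125), and stromal and endothelial markers 2 of 6 (adjusted p = 0.0582). Adjusted over the list alone, 9, 7, 10 and 3 of them were lower. CR2, a complement receptor in the last of these lists, fell by 4.24, from 102 ± 27.1 to 5.42 ± 0.280 CPM, and unlike the B cell markers it was not far lower in NAIVE replicate 2 (67.8 CPM) than in NAIVE replicate 1 (95.6 CPM). With NAIVE replicates 1, 3 and 4 left out, and the lone NAIVE library assumed to vary like the other groups, edgeR called 0 genes (1295 at an unadjusted p under 0.05, and 650 higher and 792 lower by DESeq2 on all libraries). The deeper set alone, with 1 TEFF library assumed to vary like the other groups, gave 0 (1077), and the shallower set 152 higher and 268 lower. Without TEFF replicates 1, 2 or 3 the counts were 220 and 144, 192 and 142, or 205 and 116. Without NAIVE replicates 1 or 2 they were 246 and 270, or 231 and 395, and without NAIVE replicate 3 they were 298 and 279.

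The overlap of both comparisons with NAIVE was counted next. In TFH and TEFF alike 333 genes were higher and 339 lower than in NAIVE, with 1 gene called in opposite directions. Independent lists of the same sizes would share 37.9 and 35.1 genes. Simulations without any effect against the shared NAIVE libraries (20 of them) gave 0 shared calls. With no effect simulated, shared calls are unlikely in any case, so this 0 does not measure what sharing NAIVE adds. The covariance of the fold changes was 0.89, against 0.10 in the simulations, a difference of 0.78. When the NAIVE libraries were split so that each comparison had its own pair, 57 to 192 genes were higher and 95 to 203 lower in both over 6 splits, with a covariance of 0.77 to 0.90. Without TEFF replicate 2 the number of genes higher in both was 151, without TEFF replicates 1 or 3 it was 190 or 181, and without NAIVE replicates 1 or 2 it was 209 or 183. TFH was higher than both other groups for 16 genes, where independent lists would share 1.65. Simulations without any effect gave 0, which for the same reason does not measure what sharing the TFH libraries adds. Among the 16 genes KCNK5, WNT10A, CAV1, KCNA6, FAIM2, H2AFZ, PRKCZ and FBLN7 were named by the rule. The TFH libraries are too few to split, so part of the excess may come from sharing them. The number was 0 without TEFF replicate 1 or 3, 148 without TEFF replicate 2, 3, 6 or 7 without TFH replicates 1, 2 or 3, and 6 or 5 without NAIVE replicates 3 or 4.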

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

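All tests in this part were chosen after the results they bear on had been seen, including the counts of other splits. Dixon's ratio was computed for 218 values over the 4 NAIVE libraries, the only group large enough, and 15 passed its 95% critical value, or 6.88%, where chance alone flags about 1 in 20. NAIVE replicate 2 stood apart for GATA3 (107 CPM), KCNK5 (15.2), FBLN7 (63.3), S1PR1 (179.8), CCR9 (3.55) and INSIG1 (42.0). NAIVE replicate 1 stood apart for CD6 (1422 CPM), XBP1 (172.8), FGFBP2 (13.1), PGAM1 (217), and CDH1 (4.93). NAIVE replicate 3 stood apart for IL17A (1.65 CPM) and FCER1G (2.32), and NAIVE replicate 4 for HAL (23.7) and IFNG (0.399).

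TEFF replicate 2 lay between the other TEFF libraries and TFH. Over 100 genes higher and 100 lower in TFH, chosen without that library, its levels had moved towards the TFH mean by a median of 0.46 of the distance (0.41 over the higher and 0.48 over the lower genes). TEFF replicate 3, of the same library set, had -0.17, which argues against the library set as the source, and TEFF replicate 1 had -0.08. A mixture with cells of the TFH gate may give such an equal shift in both directions, but cells of an intermediate state in that tonsil could as well, and the labels give no way to test this.

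B cell transcripts differed among the NAIVE libraries. All 15 B cell markers were lower in NAIVE replicate 2 than in each of the other 3, which is what B cells among the sorted cells would give. This count restates the pattern that prompted it, so it does not test B cells as the source. NAIVE replicates 1 and 2 belong to the same library set and differed by a median of 3.65 log2, which argues against the set as the source. CD79A was at 308 and CD22 at 209 CPM in NAIVE replicate 1, against 24.5 and 10.9 in NAIVE replicate 2. The gate on CD4 and the T cell receptor should remove B cells, and no biological explanation was tested.

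CD79A and CD8B were higher in TFH than in TEFF on average without a call. The lowest ratio of CD79A to the other B cell markers in a TFH library was 4.27 times that of NAIVE, under the bound of 5 set for excluding B cells, so B cells stay open. Plasma cell markers had a median log2 fold change of 0.78, between the bounds set, so this test leaves plasma cells open too. Library levels argue against them as the main source of CD79A. The mean log2 CPM of these markers was 2.045 in TFH replicate 3, under every TEFF library (2.101 to 2.383), with CD79A at 172.8 CPM. TFH replicates 1 and 2 lay above TEFF (2.999 and 2.962) but below NAIVE replicates 2, 3 and 4 (3.132, 4.393 and 4.095). Those NAIVE libraries had less CD79A (24.5, 128.5 and 90.7 CPM) than these TFH libraries (196.6 and 192.6 CPM). NAIVE replicate 1 had more of both. CD8B was at least 59.2 times CD8A in each TFH library, which argues against CD8 T cells, since these carry both. Reads shared with a copy of CD8B, and expression by the TFH cells themselves, were not tested.

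Other splits of the libraries were counted in the fit of 10 libraries, with the group left out of a comparison kept. For TFH against TEFF the 10 splits are too few for a share under 0.05: the real split gave 18 higher and 124 lower genes and 16 lists (1 split each), and the highest others were 0, 0 and 11. For TFH against NAIVE 1 of 35 splits, the real one, gave as many as 1375 higher and 1248 lower genes. The highest others were 0 and 0. This share is under 0.05 but is the smallest that 35 splits can give, so it argues against chance without excluding it. For the 15 lists 1 of 35 splits was as large too, but another gave 14, and leaving out TFH replicate 3 gave 7, so that count is not set apart from chance by a margin. For TEFF against NAIVE the same holds for the 412 higher and 421 lower genes (1 of 35 splits, highest others 111 and 1). The 111 came from the split that sets apart NAIVE replicates 1, 3 and 4, the NAIVE libraries with more B cell transcripts. Whether B cell genes made up the 111 was not tested. Chance cannot be excluded for the 14 lists, since 10 of 35 splits gave as many, up to 15. For the 16 genes higher in TFH than in both other groups and the 333 higher in both TFH and TEFF than in NAIVE, 1 of 60 label assignments was as large, with highest others of 2 and 54. This fit was used after it was known that fits of both groups alone call 0 genes in TFH against TEFF. In such fits every one of the 10 splits gave 0, and the real split was the largest of 35 for both comparisons with NAIVE, at 1063 and 1014 against 0 and 0, and at 449 and 560 against 122 and 2.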

How the results depend on the processing

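No gene called in the fit of 10 libraries was called in the opposite direction under any alternative run, while many counts moved. Without a call, up to 11 of 1643 such genes took the other sign, in TFH against NAIVE with 10 CPM required in 3 libraries. The cause was not tested except where fewer libraries or genes entered the fit. The library set alternatives, and those that leave out TEFF replicate 2 with the set as a covariate or NAIVE replicates 1, 3 and 4, were chosen after seeing the data. DESeq2 called 255 higher and 434 lower in TFH against TEFF, 650 and 792 in TEFF against NAIVE, 227 higher in TFH than in both other groups and 522 higher in both TFH and TEFF than in NAIVE. In TFH against TEFF limma voom called 53 higher (52 higher than in both other groups), log2(RPKM + 1) 129 (and 129), and log2(RPKM + 0.1) 76 (and 75). The share higher among the calls in that comparison was 12.7% in edgeR, 9.70% with RLE size factors, 37.0% with DESeq2, 51.6% with log2(RPKM + 1) and 35.7% with log2(RPKM + 0.1). The second principal component held 30.1% with log2(RPKM + 1). With 10 CPM required in 3 libraries, and so fewer genes, the counts were 7 and 77 in TFH against TEFF, 848 and 668 in TFH against NAIVE, 240 and 181 in TEFF against NAIVE, 7 higher in TFH than in both and 202 higher in both than in NAIVE. With only both groups in the fit, TFH against TEFF gave 0 and 0, and 0 genes were higher in TFH than in both. The replicate number as a block gave 0 and 0 in TFH against TEFF, 825 higher in TFH against NAIVE, 124 and 134 in TEFF against NAIVE, 0 higher in TFH than in both and 108 higher in both than in NAIVE. The numbers did not pair the libraries: correlations of same-numbered deviations ran from -0.32 to 0.45 in TFH and TEFF, from 0.05 to 0.10 in TFH and NAIVE and from -0.30 to 0.37 in TEFF and NAIVE. With the library set as a covariate 90 and 282 were called in TFH against TEFF, 1889 were lower in TFH against NAIVE, 88 were higher in TFH than in both and 516 higher in both than in NAIVE. With TEFF replicate 2 left out as well these were 295 and 373 in TFH against TEFF, 242 lower in TEFF against NAIVE and 277 higher in TFH than in both, and the log2 fold change of CD8B in TEFF against NAIVE turned to -1.85. Each library set alone leaves 1 library of TEFF (deeper) or TFH (shallower), assumed to vary like the other groups. The deeper libraries alone gave 0 and 0 in TFH against TEFF, 436 and 387 in TFH against NAIVE, 0 and 0 in TEFF against NAIVE and 0 for both shared counts. There the immediate early list in TEFF against NAIVE turned to a median of 0.40. The shallower libraries alone gave 0 and 0, 495 and 699, and 152 and 268 in the same order, 0 higher in TFH than in both and 123 higher in both than in NAIVE. They turned cell cycle to -0.30 against TEFF and -0.28 against NAIVE, and glycolysis to -0.049 in TFH against TEFF. With NAIVE replicates 1, 3 and 4 left out, and NAIVE replicate 2 assumed to vary like the other groups, the counts were 0 and 0, 189 and 240, and 0 and 0, both shared counts were 0, and 7 lists were called in TFH against NAIVE. In that fit the B cell markers turned to 0.56 in TFH against NAIVE. The median of the interferon stimulated list in TEFF against NAIVE was -0.57 there, and -0.076 in the fit of 10 libraries. With an estimated correlation 6, 1 and 3 lists were called in TFH against TEFF, TFH against NAIVE and TEFF against NAIVE, and fry called 8 in TFH against TEFF. Leaving out each library in turn gave 0 to 162 higher and 0 to 194 lower in TFH against TEFF, 915 to 1486 and 831 to 1547 in TFH against NAIVE, 192 to 492 and 116 to 507 in TEFF against NAIVE. It gave 0 to 148 higher in TFH than in both, 151 to 375 higher in both than in NAIVE, and 13 to 19, 7 to 16 and 14 to 16 lists in the same order of comparisons. CD8B in TEFF against NAIVE turned to -1.86 without TEFF replicate 2 and was at most 0.67, without TEFF replicate 3. Among the named genes in TFH against TEFF, 379 of 1575 values under alternatives lost the call and 33 gained it, in TFH against NAIVE 375 of 2688 lost it, and in TEFF against NAIVE 469 of 2048 lost it and 10 gained it. Depth set a limit of 0.147 CPM on a count of 0 in the shallowest library.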

Other observations

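Families of genes that share a symbol stem were tested in an analysis chosen after seeing the data, with camera at the preset correlation over 350 families of at least 6 members. In TFH against TEFF 14 families were called, in TFH against NAIVE 3 and in TEFF against NAIVE 4, and 0 of these held with an estimated correlation. Of the 8 integrin alpha chain genes in the ITGA family, 2 were lower in TFH than in TEFF (median -1.16, adjusted p = 8.71e-04 by camera, and adjusted p = 0.764 with an estimated correlation). Against NAIVE 4 of 8 were lower in TFH and 1 higher (median -1.46, adjusted p = 0.00657 by camera, and adjusted p = 0.98 with an estimated correlation). ITGAL, an alpha chain gene outside this family, went the other way, at 2672 ± 300 CPM in TFH, 1642 ± 147 in TEFF and 978.5 ± 142 in NAIVE. ITGA1, a collagen-binding chain, fell by 5.82 against TEFF and fell by 7.65 against NAIVE, and ITGA6, a laminin-binding chain, fell by 2.20 and by 4.70. Potassium channel genes (KCNK) had 3 of 6 higher in TFH than in NAIVE, with KCNK5 rising by 4.16, KCNK1 by 3.91 and KCNK15 by 3.02 (adjusted p = 0.98 for the family with an estimated correlation).

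G protein-coupled receptor genes with the stem GPR had 4 of 48 lower in TFH than in TEFF, with GPR15, a gut homing receptor, falling by 6.31, GPR171 by 3.16 and GPR65 by 2.09 (adjusted p = 0.764 for the family with an estimated correlation). Guanylate binding protein genes (GBP, 1 of 6 lower), GIMAP genes (1 of 7) and Schlafen genes (SLFN, 1 of 6) had medians of -1.87, -1.36 and -1.44, each with adjusted p = 0.998 with an estimated correlation. Mitochondrial ribosomal protein genes (MRPL) had a median of 0.36 with 0 of 49 called by edgeR. Ribosomal protein genes (RPL) had a median of -0.56 in TEFF against NAIVE with 0 of 59 called.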
